A study of Homo sapiens with 8 samples.

How the data were processed

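Gene expression was measured by RNA sequencing in 8 libraries of HEK 293T cells, a transformed human embryonic kidney line, 4 treated with Val-boroPro and 4 with DMSO, the solvent control, each for 48 hours. Per the labels, cells were grown in DMEM with fetal bovine serum, RNA was taken with a column kit, and 500 ng of total RNA went through poly(A) selection, Illumina TruSeq preparation and 8 cycles of PCR. The deposited values are a signal per gene, which the authors made by dividing the read count of each gene by 1 size factor per library with DESeq, version not given. The read aligner, the read counter and the annotation are not stated in the sources used here. The processing notes name the mouse build mm9, whereas the rows carry human Ensembl gene identifiers, so no positions are given. Whether the libraries kept strand information is not stated either, so reads of overlapping genes on opposite strands may be shared.

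The table had 26265 rows, of which 405 held no read in any library. Every value was a whole multiple of the smallest step of its library, within a tolerance of 0.001 reads, so whole reads were recovered by multiplying by the size factor. Size factors ran from 1.08 to 1.34 with a geometric mean of 1.16. Gene symbols that a spreadsheet had turned into dates in 24 rows were restored from the identifiers, and 78 rows shared a symbol with another row. Gene type, transcript GC content, transcript length, overlaps and chromosome came from GENCODE release 29 by gene identifier alone, which covered 25262 rows.

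Val-boroPro was compared with DMSO by limma 3.58.1 with an intensity trend, two-sided, on the log2 of the value plus a pseudocount of 1, with group as the only term. The 16513 genes with a mean of at least 10 over the 8 libraries were tested, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. Calls at an absolute log2 fold change of at least 1 were also counted. The lists numbered 30 and held 681 genes found in the table. The 28 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the 28 lists, with camera at an estimated correlation and fry beside it. Members were also counted as called when adjusted over the list alone. Library measures were compared with two-sided exact permutation tests of the group means, adjusted over 5 measures.

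The comparison, tests, lists and the rule for named genes were set before the data were examined. The rule took 12 genes in each direction with the largest log2 fold change among called genes with a mean of at least 50, no overlap between the groups and an established symbol. To these it added the 4 members of each tested list with the smallest p, from which up to 4 are printed, and DPP8, DPP9, DPP4, DPP7, FAP, PREP, NLRP1, CARD8 and CASP1 at any value. FAP was not among the rows and is not analysed here. Genes named outside the rule are marked as chosen after their values were seen.

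Alternatives set beforehand were pseudocounts of 0.5 and 8, no filter and a mean of at least 50, TMM factors, quantile normalization, median centring, limma without trend and with robust variance estimates, edgeR 4.0.16 quasi-likelihood tests and DESeq2 1.42.0 on the recovered reads, the replicate number as a block, each library left out in turn, and an adjusted p below 0.01. Alternatives chosen after seeing the data were the removal of the trend of each library with transcript GC content and log2 length (splines with 5 degrees of freedom, 16080 genes), also with each library left out, and fits without DMSO 4 and Val-boroPro 1 or without DMSO 3 and DMSO 4. The tests were tried on simulated counts for 16513 genes with a biological coefficient of variation of 0.05 and 200 changed genes. limma with trend recovered 68% of 50 genes changed 1.25-fold and 96% of 50 genes changed 2-fold, with 10 false calls. A GC trend added to the simulated libraries gave 144 false calls, and the fit with trends removed gave 4. The added trend was weaker in DMSO 3 and DMSO 4 than in the data, so 144 does not measure the effect of GC bias here. It was also linear in the GC content used to remove it, so its removal was given in advance.

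Total reads ran from 32509734 to 40428711 per library. PCR copies were not told apart from separate molecules, so intervals and limits from read counts cover counting error only. The labels call the samples replicates without saying whether each was a separate culture, so the p-values may measure technical spread. Computations used R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.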

Results

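RNA of HEK 293T cells was sequenced after 48 hours with Val-boroPro (4 libraries) or with DMSO (4 libraries). Val-boroPro is a boronic acid dipeptide that inhibits serine proteases cleaving after proline, among them DPP8 and DPP9. The DMSO libraries held 40428711, 35053304, 34192806 and 34264187 reads and the Val-boroPro libraries 35066169, 34024115, 32509734 and 35914580 reads. Gene values are size-factor-scaled read counts as mean ± SD with n = 4 per group. Log2 fold changes are Val-boroPro over DMSO with their standard error (SE). The p-values are limma's, adjusted over 16513 genes, unless another test is named. The comparison asked how transcription changed in the 48 hours with Val-boroPro.

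Most transcripts stayed near their DMSO level, and the changes that passed the test were small. The gene with the smallest p was HSPA1B, the stress-inducible HSP70 chaperone, which rose 1.42-fold. Genes of the heat shock response, cytosolic ribosomal proteins, proteasome subunits and aminoacyl-tRNA synthetases were among the lists with higher values in Val-boroPro, and the mitochondrially encoded transcripts had lower ones. These lists passed camera at the preset correlation but not with an estimated correlation (adjusted p = 0.53 for each). The transcripts of DPP8 and DPP9, targets of the compound, did not pass the test with all 8 libraries. Of the 16513 genes tested, 1533 were called, 816 higher and 717 lower in Val-boroPro. The median absolute log2 fold change of the called genes was 0.21 and its 95th percentile 0.54. Only 4 called genes had an absolute log2 fold change of at least 1, all with low values and named after their values were seen. HSPA1A, whose groups overlapped, rose from 6.40 ± 4.97 to 14.6 ± 3.92, and KIF12, a kinesin, fell from 21.1 ± 2.86 to 10.2 ± 3.23. RP13-39P12.3 and RP11-30L15.4 fell too (log2 -1.02 and -1.04). The values of both groups did not overlap for 2955 genes, 17.9% of those tested, where chance gives 2.86% on average. All genes share the same 8 libraries and their trends, so the excess over this share is no test of the treatment. The count of 1533 depended on single libraries. It was 3106 without DMSO 1, 81 without DMSO 3 and 523 without DMSO 4. It was 6, 112, 2371 and 29 without Val-boroPro 1, 2, 3 and 4. It was 62 without DMSO 4 and Val-boroPro 1 together and 336 without DMSO 3 and DMSO 4 together. The 4 large changes numbered 2 without DMSO 3, 1 without DMSO 4 and 0 without Val-boroPro 1, 2 or 4. TMM factors gave 878 genes (308 higher, 570 lower) and edgeR 796 (273 higher, 523 lower). The count was 803 with no filter, 310 after quantile normalization, 5 without the intensity trend and 7 at an adjusted p below 0.01. Once trends with GC content and length were removed it was 2177 (1603 higher, 574 lower), with 988 genes shared.

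The heat shock response, the set of chaperones that refold damaged proteins, had the highest median log2 fold change of the 28 tested lists, 0.18. Of its 19 tested members 14 rose, none fell and 5 did not pass (17 rose adjusted over the list alone). HSPA1B (ENSG00000204388.5) went from 7978 ± 287 to 11294 ± 350.3, a log2 fold change of 0.50 (SE 0.040, adjusted p = 4.0e-06). DNAJB1, an HSP40 co-chaperone that directs clients to HSP70, rose from 3866 ± 93.9 to 4742 ± 203 (log2 0.29, SE 0.041, adjusted p = 0.0046). HSPA8, the constitutive HSP70, rose from 72229.6 ± 3122 to 84426 ± 4065 (adjusted p = 0.020), and CHORDC1, an HSP90 co-chaperone, from 5201 ± 319 to 6088 ± 316 (adjusted p = 0.021). For these 4 genes every Val-boroPro library lay above every DMSO library. The list passed camera with an adjusted p of 1.8e-10 and fry with 0.030, and it did not pass with an estimated correlation (adjusted p = 0.53). Leaving out DMSO 1 to 4 and then Val-boroPro 1 to 4 in turn, 18, 11, 3, 10, 2, 2, 16 and 2 members were called. HSPA1B and DNAJB1 kept the call each time. HSPA1A and HSPA1B have nearly identical sequences, DNAJB1 overlaps TECR and HSPA8 has processed pseudogenes, so reads may be shared.

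**Figure D1:**
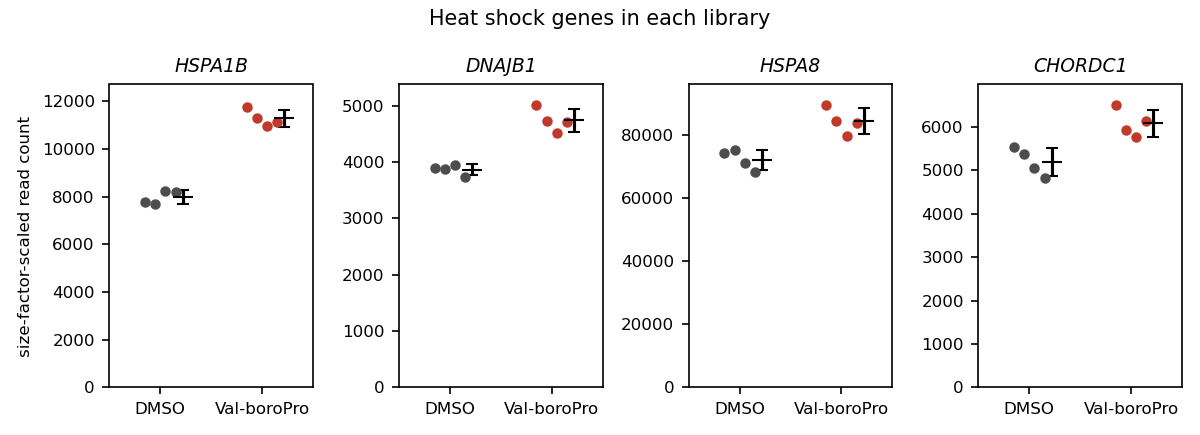
Size-factor-scaled read counts of HSPA1B, DNAJB1, HSPA8 and CHORDC1 in each library, with DMSO in grey, Val-boroPro in red, and the mean and SD of the 4 libraries in black. Each vertical axis starts at 0, and HSPA1B shows the largest relative step of the 4 genes, from 7978 to 11294.

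Among genes outside the heat shock list, the largest increases that met the rule for named genes were moderate. SYTL5, a synaptotagmin-like protein, rose 1.38-fold, from 143 ± 14.9 to 197 ± 14.8 (adjusted p = 0.018), and RCAN2, a regulator of calcineurin, rose 1.32-fold (adjusted p = 0.025). HRK, a BH3-only activator of apoptosis, rose from 353 ± 17.9 to 448 ± 17.8 (adjusted p = 0.013), and DUSP16, a phosphatase of MAP kinases, from 1089 ± 30.8 to 1363 ± 43.5 (adjusted p = 0.0046). KLHL4, ANXA3, EMILIN2, ANXA1, KTN1-AS1, TMOD1 and ASXL3 rose with log2 fold changes of 0.38, 0.38, 0.34, 0.33, 0.32, 0.31 and 0.31. The 12 genes that this rule named for their decreases had a median transcript GC content of 64.2%. It was 44.9% for the 12 named for their increases and 49.6% for all tested genes. SLC26A10, of an anion transporter family, fell from 81.0 ± 6.64 to 49.1 ± 7.53 (log2 -0.72, SE 0.13, adjusted p = 0.013). GPT, alanine aminotransferase, fell from 101.2 ± 9.16 to 62.1 ± 8.75 (adjusted p = 0.012), and RHBDL1, a rhomboid-like protein, from 115 ± 14.8 to 70.7 ± 5.96 (adjusted p = 0.012). MRPS24, a mitochondrial ribosomal protein, fell from 104 ± 45.1 to 59.1 ± 4.19 (log2 -0.71, SE 0.20, adjusted p = 0.042), its log2 running from -0.91 without DMSO 1 to -0.45 without DMSO 4 (adjusted p = 0.0037 and 0.082). SCARNA15, MEGF6, PNPLA7, RAET1G, IDUA, SCNN1D, ELFN2 and ICAM5 fell with log2 fold changes of -0.71, -0.69, -0.63, -0.60, -0.60, -0.57, -0.57 and -0.57. Once GC and length trends were removed, ANXA3 (log2 0.31, SE 0.11, adjusted p = 0.065) and ANXA1 (0.25, SE 0.096, 0.078) no longer passed, their changes within 1 SE of those before (SE 0.11 and 0.099). IDUA lost the call with a smaller change (log2 -0.31, SE 0.12, adjusted p = 0.085, and log2 -0.60, SE 0.14 before). The log2 of GPT, MEGF6, RHBDL1, SCNN1D, ELFN2 and ICAM5 went to -0.46, -0.41, -0.42, -0.32, -0.38 and -0.31, smaller by over 1.5 times, with the call kept. Of these genes and HSPA1B, 24 in all, 10 kept the call without DMSO 3, 2 without Val-boroPro 1 (HSPA1B and DUSP16), 13 without Val-boroPro 2 and 6 without Val-boroPro 4. KTN1-AS1, TMOD1, SLC26A10, SCARNA15, GPT, RAET1G and IDUA overlap other expressed genes, so their reads may not be theirs alone.

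Genes of protein synthesis and breakdown were higher as groups by camera at the preset correlation, but not with an estimated correlation (adjusted p = 0.53 for each list) or by fry (0.067, 0.067 and 0.072 for ribosomal proteins, synthetases and proteasome). Of 36 cytosolic ribosomal protein genes 14 rose and 22 did not pass (21 rose adjusted over the list alone), with RPSA going from 20067 ± 1050.1 to 23458 ± 912 and RPS6 from 39856 ± 2133 to 46022 ± 2399. Of 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 7 rose and 13 did not pass (13 rose adjusted over the list alone), GARS from 6777 ± 173 to 7648 ± 429.7 and AARS from 7021 ± 87.1 to 7702 ± 210.0. Of 32 proteasome subunits 3 rose and 29 did not pass (5 rose adjusted over the list alone), among them PSMD11 from 7089 ± 144 to 7810.3 ± 332 and PSMB7, whose groups overlapped, from 5105 ± 172 to 5679 ± 377. The median log2 fold changes were 0.12 for ribosomal proteins, 0.12 for synthetases and 0.10 for the proteasome. Camera at the preset correlation gave adjusted p-values of 3.9e-07, 1.8e-04 and 1.6e-05. For all 6569 protein-coding genes with a mean over 1000 the median was 0.066. Camera set each list against all other tested genes, not against genes of like abundance. Once GC and length trends were removed, 27 ribosomal proteins, 8 synthetases and 9 of 31 proteasome subunits were called higher. The list medians were smaller in that fit, at 0.11, 0.073 and 0.060, and that of protein-coding genes with a mean over 1000 was 0.047. With DMSO 1 to 4 and then Val-boroPro 1 to 4 left out in turn, the called ribosomal proteins numbered 18, 8, 1, 4, 0, 0, 21 and 0. In the same order the synthetases numbered 11, 5, 0, 2, 0, 0, 12 and 0 and the proteasome subunits 7, 1, 0, 0, 0, 0, 10 and 0. Ribosomal protein genes have many processed pseudogenes, so their reads may be shared.

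By camera at the preset correlation, cell cycle genes and nuclear genes of oxidative phosphorylation were also higher as groups, and mitochondrially encoded transcripts were lower. None of these 4 lists passed with an estimated correlation (adjusted p = 0.53 for each) or by fry (0.067 for each higher list and 0.19 for the mitochondrial one). Of 26 S phase genes 5 rose and 21 did not pass (12 rose adjusted over the list alone), including SLBP, the histone mRNA binding protein, from 3161 ± 110.0 to 3596 ± 160.2 and MCM6, of the replicative helicase, from 9237 ± 372 to 10310.4 ± 492. Of 26 genes of the G2 and M phases 2 rose and 24 did not pass (12 rose adjusted over the list alone), NUSAP1 from 4487 ± 192 to 5005 ± 157 and CKAP2, whose groups overlapped, from 7981 ± 415 to 8839 ± 381, both with products on the mitotic spindle. Of 33 nuclear genes of oxidative phosphorylation 4 rose, 2 fell and 27 did not pass (16 and 2 adjusted over the list alone). UQCRH, of complex III, rose from 6558 ± 212 to 7370.0 ± 407, while NDUFV1 and NDUFS7, both of complex I, fell (log2 -0.18 and -0.39), NDUFS7 being named after its values were seen. Without DMSO 4 the log2 of NDUFS7 was -0.22 (adjusted p = 0.052). Both calls ended once GC and length trends were removed, with smaller changes (log2 -0.040 and -0.15, SE 0.029 and 0.061, adjusted p = 0.38 and 0.094, with SE 0.053 and 0.12 before). Of the 13 mitochondrially encoded transcripts 1 fell, MT-ND4L, from 20718 ± 1808 to 17977 ± 438 with overlapping groups and an overlap with MT-ND4, and 12 did not pass (7 fell adjusted over the list alone). MT-CO1, the most abundant of those named, had 211795 ± 16814 in DMSO and 189612 ± 6830.4 in Val-boroPro (adjusted p = 0.074). Mitochondrially encoded reads made up 3.74% ± 0.28 of all reads in DMSO and 3.35% ± 0.06 in Val-boroPro (two-sided exact permutation p = 0.057, adjusted 0.095). The median log2 fold changes were 0.10, 0.10, 0.11 and -0.13 for S phase, G2 and M phase, oxidative phosphorylation and mitochondrial transcripts. Camera at the preset correlation gave adjusted p-values of 0.0021, 9.8e-05, 5.9e-04 and 1.6e-04. The median of all 6569 protein-coding genes with a mean over 1000 was 0.066, and camera did not set the lists against genes of like abundance. With GC and length trends removed, 6 of 25 S phase genes, 7 of the G2 and M phases and 9 of oxidative phosphorylation were called higher, and 10 of the 13 mitochondrial transcripts lower (list median -0.18). The medians of the 3 higher lists, in the same order, were smaller in that fit, at 0.081, 0.066 and 0.068. That of protein-coding genes with a mean over 1000 was 0.047. The called S phase genes numbered 11, 3, 0, 1, 0, 0, 12 and 0 with DMSO 1 to 4 and then Val-boroPro 1 to 4 left out in turn. In the same order there were 10, 5, 0, 0, 0, 0, 10 and 0 called genes of the G2 and M phases. For oxidative phosphorylation these counts were 14, 5, 0, 0, 0, 0, 11 and 0, and for mitochondrial transcripts 1, 0, 1, 1, 0, 0, 1 and 0.

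The remaining 20 tested lists did not pass camera, though some of their members changed. In the extracellular matrix and TGF-beta list 5 of 22 members fell and none rose (adjusted p = 0.053 for the list, 7 fell and 1 rose adjusted over the list alone). The collagens COL6A1 and COL5A1 fell from 2559 ± 284 to 1983 ± 214 and from 597 ± 24.9 to 487 ± 35.4 (log2 -0.37 and -0.30). SPARC, a matrix protein, fell by 0.16 on the log2 scale (SE 0.042). Once GC and length trends were removed the log2 of COL6A1 and COL5A1 was -0.17 and -0.16, with the call kept, and that of SPARC -0.095 (SE 0.036), with the call ended (adjusted p = 0.078). In the autophagy and lysosome list 5 of 28 members fell and 1 rose (list 0.053, 7 and 2 adjusted over the list alone). CTSD, a lysosomal protease, and ULK1, a kinase that starts autophagy, fell (log2 -0.31 and -0.30, SE 0.081 and 0.082), CTSD with overlapping groups. Once the trends were removed both changes were smaller (log2 -0.10 and -0.064, SE 0.036 and 0.034) and lost the call (adjusted p = 0.064 and 0.21). MAP1LC3B, a protein of the autophagosome membrane, rose from 3416 ± 184 to 3844 ± 152. Of 19 NRF2 targets, genes of the antioxidant response, 5 rose and none fell (list 0.071, 7 rose adjusted over the list alone). PRDX1 went from 17842 ± 867 to 20769 ± 1103 and TXNRD1 from 6812 ± 259 to 7618 ± 394. Of 28 hypoxia and glycolysis genes 4 rose and 1 fell (list 0.078, 5 and 3 adjusted over the list alone), the glycolytic enzymes LDHA and TPI1 rising 1.16 and 1.12-fold. Of 25 ribosome biogenesis and MYC targets 2 rose and none fell (list 0.071, 3 rose adjusted over the list alone), ODC1 and NME1 by 1.14 and 1.12-fold. Once GC and length trends were removed, camera passed for the matrix (adjusted p = 0.026), NRF2 (0.0024), ribosome biogenesis (0.0024) and hypoxia (0.0056) lists and not for autophagy and lysosome (0.063). The called members were then 3 higher and 6 lower for the matrix, 8 and 0 for NRF2, 5 and 0 of 24 for ribosome biogenesis, 9 and 1 for hypoxia and 2 and 3 for autophagy. With an estimated correlation none of the 5 passed there (0.43, 0.43, 0.52, 0.43 and 0.43). All 5 lists also passed camera without DMSO 4 (0.015, 0.020, 0.047, 0.042 and 0.015) and without Val-boroPro 3 (0.015, 0.033, 0.015, 0.029 and 0.029). The matrix list passed without Val-boroPro 2 (0.044) and the NRF2, ribosome biogenesis and hypoxia lists without DMSO 3 (0.030 for each). With DMSO 1 to 4 and then Val-boroPro 1 to 4 left out in turn, the called matrix genes numbered 8, 6, 0, 4, 0, 2, 5 and 0. Called autophagy and lysosome genes numbered 8, 6, 0, 1, 0, 0, 8 and 0 in this order. The counts were 6, 4, 1, 2, 0, 0, 7 and 0 for NRF2 targets and 7, 3, 0, 2, 0, 0, 6 and 0 for hypoxia and glycolysis. They were 4, 2, 0, 1, 0, 0, 5 and 0 for ribosome biogenesis.

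Some genes of the stress, lipid and signalling lists were called with all 8 libraries. Their numbers are to be read against the 1533 called of all 16513 genes tested. Of 33 genes of the integrated stress response 3 rose and none fell (list 0.71, 3 adjusted over the list alone). ATF3, a stress-induced transcription factor, went from 901 ± 49.9 to 1104 ± 27.9 (adjusted p = 0.012), MTHFD2, of mitochondrial folate metabolism, from 5866 ± 233 to 6539 ± 271, and PSAT1, of serine synthesis, from 6594 ± 334 to 7386 ± 333. Once GC and length trends were removed, 10 of the 33 rose and the list passed camera (adjusted p = 0.0021), but not with an estimated correlation (adjusted p = 0.39). Of 24 endoplasmic reticulum chaperone and unfolded protein response genes 2 rose and 1 fell (list 0.71, 2 and 3 alone). XBP1, a transcription factor of this response, rose from 2955 ± 99.1 to 3497 ± 147, and SYVN1, a ubiquitin ligase of the same compartment whose groups overlapped, fell by 0.18 on the log2 scale. Of 24 cholesterol synthesis genes 3 rose and 1 fell (list 0.91, 4 and 1 alone), including FDFT1, 1.13-fold higher, and CYP51A1 (log2 -0.33, and -0.21 with adjusted p = 0.13 without DMSO 4). None of 13 fatty acid synthesis genes was called by limma (list 0.99, 1 higher and 2 lower alone), with 5 at an unadjusted p below 0.05, 0 called by edgeR and 1 by DESeq2. FASN had 14994 ± 3497 in DMSO and 11932 ± 566 in Val-boroPro (log2 -0.30, adjusted p = 0.065). Its log2 ran from -0.40 without DMSO 1, where it passed (0.0068) as it did without DMSO 2 (0.029), to -0.17 without DMSO 4 (0.11). Of 23 apoptosis regulators 3 rose and none fell (list 0.32, 3 alone). HRK and MCL1, which opposes apoptosis (log2 0.14), were among them. Of 24 p53 targets 1 rose, C12orf5, and 1 fell, PLK3 (log2 -0.33, SE 0.098), whose call ended once the trends were removed (log2 -0.23, SE 0.097, adjusted p = 0.12, list 0.99, 1 and 1 alone). Of 22 immediate early genes JUN rose 1.18-fold (log2 0.24) and NR4A1 fell by 0.40 on the log2 scale (list 0.71, 4 and 2 alone). With the trends removed the log2 of JUN was larger (0.32) and that of NR4A1 smaller in size (-0.24), both with the call kept. Of 15 NF-kB targets SOD2, which overlaps WTAP, rose (log2 0.14, list 0.91, 1 alone). Here "alone" stands for adjusted over the list alone, for higher and then lower members. The cholesterol list had a median of -0.0062 and a mean of -0.0036 although camera ranked it higher, and the fatty acid and p53 lists had medians of 0.019 and 0.031 but means of -0.013 and -0.018. Once GC and length trends were removed, higher and lower calls were 2 and 2 for endoplasmic reticulum genes, 4 and 2 for cholesterol, 1 and 0 of 12 for fatty acid genes, 4 and 0 for apoptosis, 5 and 0 for p53, 4 and 1 for immediate early genes and 1 and 0 for NF-kB. Called genes of the integrated stress response numbered 5, 4, 1, 1, 0, 1, 7 and 0 with DMSO 1 to 4 and then Val-boroPro 1 to 4 left out in turn. In this order the counts were 7, 5, 1, 1, 0, 1, 4 and 1 for endoplasmic reticulum genes and 5, 5, 0, 1, 0, 0, 3 and 0 for cholesterol synthesis. For fatty acid synthesis they were 3, 2, 0, 0, 0, 0, 2 and 0 and for apoptosis regulators 8, 3, 1, 1, 0, 1, 3 and 0. For p53 targets they were 4, 1, 0, 1, 0, 0, 3 and 0, for immediate early genes 3, 3, 1, 2, 0, 0, 2 and 0 and for NF-kB targets 1, 0, 0, 0, 0, 0, 1 and 0.

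The post-proline proteases include the known targets of Val-boroPro, and the inflammasome is a complex that starts inflammatory cell death. Of both lists only DPP7 and TXN were called with all 8 libraries. DPP8 (ENSG00000074603.14) had 2485 ± 115 in DMSO and 2475 ± 98.7 in Val-boroPro (log2 -0.0054, SE 0.045, adjusted p = 0.95). DPP9 (ENSG00000142002.12) had 2355 ± 251 and 2155 ± 31.5 (log2 -0.12, SE 0.059, adjusted p = 0.16). With 1 library left out the log2 of DPP9 ran from -0.18 without DMSO 1, where it passed (adjusted p = 0.028), to -0.064 without DMSO 4. Their signs turned with median centring (DPP8, log2 0.011) and once GC and length trends were removed (DPP9, log2 0.024). With those trends removed the log2 of DPP8 was -0.077 (SE 0.031, adjusted p = 0.092), lower than before and not past the threshold. PREP had 2734 ± 96.6 and 2937 ± 136 (adjusted p = 0.12) and DPP4 had 94.5 ± 12.1 and 85.7 ± 13.5 (adjusted p = 0.46). DPP7, a lysosomal member, was the 1 called gene among the 7 post-proline proteases tested, falling from 135 ± 34.8 to 94.6 ± 7.61 (log2 -0.48, SE 0.14, adjusted p = 0.044). Its call ended once GC and length trends were removed (log2 -0.22, SE 0.094, adjusted p = 0.12). The list of post-proline proteases had an adjusted p of 0.65, with 1 member higher and 1 lower adjusted over the list alone. Of 21 other peptidases METAP1 rose 1.11-fold and NPEPL1, which overlaps a readthrough transcript, fell by 0.31 on the log2 scale (SE 0.096, list 0.71, 8 higher and 4 lower adjusted over the list alone). The call of NPEPL1 ended once the trends were removed (log2 -0.15, SE 0.081, adjusted p = 0.21), where 2 other peptidases were higher and 2 lower and 1 post-proline protease other than DPP7 was lower. METAP1 kept the call there with a smaller change (log2 0.093, SE 0.029, and log2 0.15, SE 0.041 before). Of the 8 tested inflammasome and pyroptosis genes TXN, thioredoxin, rose from 7909 ± 292 to 9096 ± 532 (list 0.91, median 0.052, mean -0.0023, 1 higher adjusted over the list alone). NLRP1, a sensor of the inflammasome, had 312 ± 21.7 and 279 ± 9.09 (adjusted p = 0.13) and CARD8, another sensor, 1248 ± 93.1 and 1324 ± 35.5 (adjusted p = 0.27). CASP1, the inflammasome protease, had 1 read among 143939008 in DMSO, 6.9e-07% of reads (95% Clopper-Pearson interval 1.8e-08% to 3.9e-06%). It had 0 reads among 137514598 in Val-boroPro, which allows a share of up to 2.2e-06%. With DMSO 1 to 4 and then Val-boroPro 1 to 4 left out in turn, the called post-proline proteases numbered 3, 1, 0, 0, 0, 0, 1 and 0. Called other peptidases numbered 7, 3, 0, 0, 0, 0, 7 and 0 and called inflammasome genes 1, 1, 0, 1, 0, 0, 1 and 0.

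The neuronal and adrenal list and the fibroblast list did not pass camera, and 2 of their genes were called. Of 18 neuronal and adrenal genes typical of HEK 293 lines UCHL1, a neuronal ubiquitin hydrolase, rose 1.11-fold and LHX1, a developmental transcription factor, fell by 0.25 on the log2 scale (list 0.31, 1 and 1 adjusted over the list alone). None of 8 fibroblast markers was called by limma, with 2 at an unadjusted p below 0.05, 0 called by edgeR and 1 by DESeq2, COL1A1 having 555 ± 89.6 and 450.0 ± 40.9 (adjusted p = 0.053, list 0.099, 1 lower adjusted over the list alone). The fibroblast list had a median log2 fold change of -0.21, the largest absolute median of the 28 lists, with 7 of its 8 members below 0. None of 22 interferon-stimulated genes was called by limma over all genes or adjusted over the list alone, with 5 at an unadjusted p below 0.05 and 0 called by edgeR or DESeq2, OAS3 having 343 ± 26.1 and 303 ± 10.9 (adjusted p = 0.10, list 0.10). None of 12 genes in the histone list was called by limma in either count (list 0.91), with 1 at an unadjusted p below 0.05 and 0 called by edgeR or DESeq2. The RNA was poly(A)-selected, and HIST1H2AG, HIST2H2BE and HIST1H4H had DMSO means of 113, 177 and 53.7, against 7207 for H1F0. The absence of calls is therefore no evidence that histone transcripts were unchanged. Only 2 macrophage and 3 lymphocyte markers reached the minimum mean, too few for camera, with 0 called by limma, edgeR or DESeq2, 0 at an unadjusted p below 0.05 and a highest macrophage marker mean of 24.8 for CD33. Called neuronal and adrenal genes numbered 2, 2, 0, 0, 0, 0, 2 and 0 with DMSO 1 to 4 and then Val-boroPro 1 to 4 left out in turn. A fibroblast marker, COL1A1, was called without DMSO 1 (adjusted p = 0.013) and without DMSO 2 (0.029) and not without Val-boroPro 1 (0.19, the highest), and 1 interferon-stimulated gene and 1 histone gene without Val-boroPro 3.

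**Figure D2:**
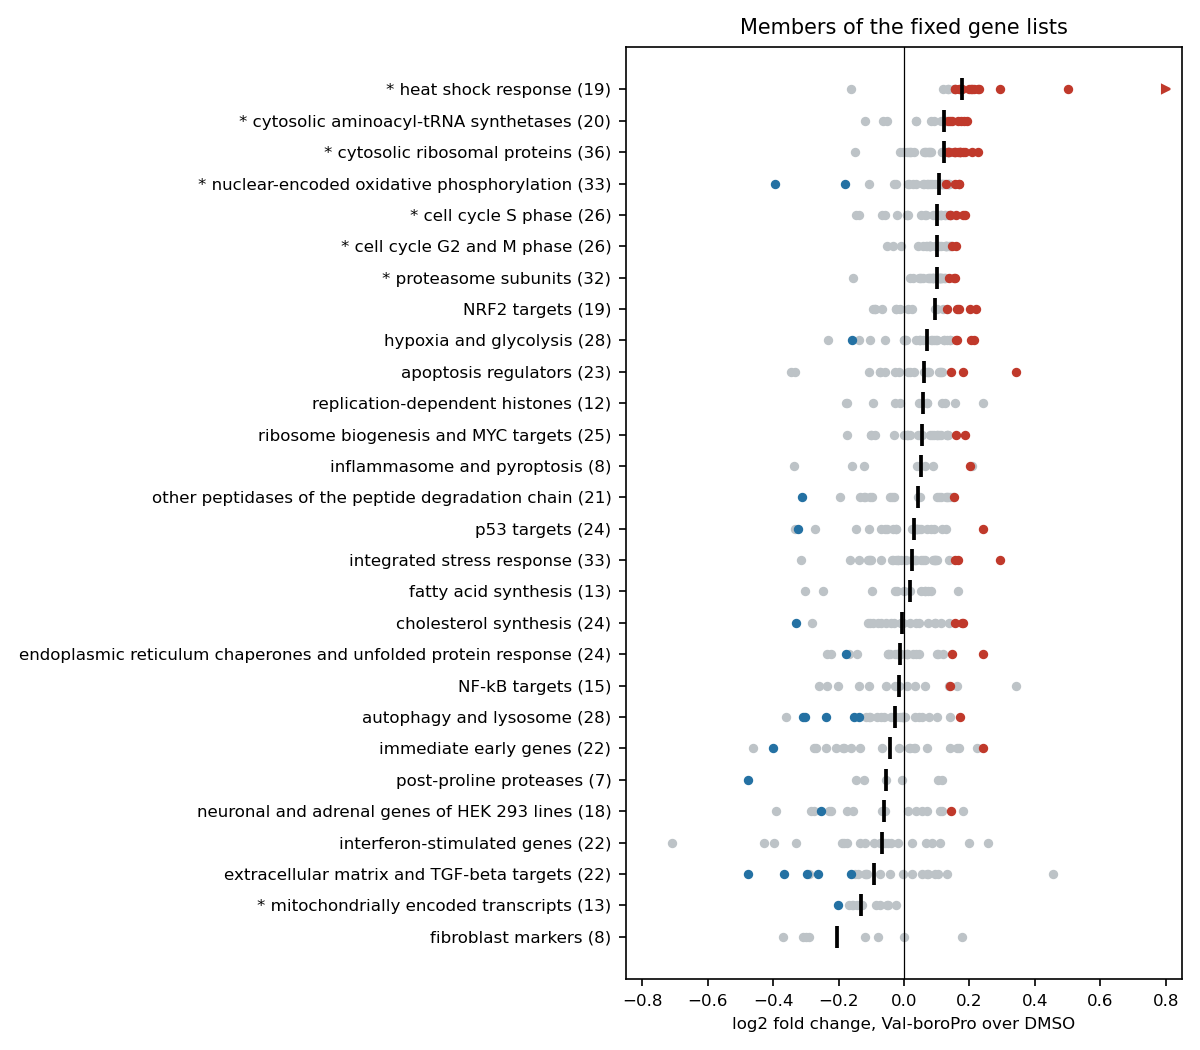
Log2 fold change (Val-boroPro over DMSO) of each tested member of the 28 tested gene lists, with called members in red (higher) or blue (lower), others in grey, the list median as a black bar and the number of members in brackets. The 8 lists past camera at the preset correlation carry a star, none of them passing with an estimated correlation, the axis ends at 0.8 and 1 member beyond it is drawn as a triangle.

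GC-rich genes had lower values in Val-boroPro than in DMSO. The median transcript GC content was 61.4% for genes called lower, 45.1% for genes called higher and 49.6% for all tested genes. The median log2 fold change was 0.07 in the decile of genes with the least GC and -0.22 in the decile with the most. Across genes, which are not independent replicates, the log2 fold change correlated with GC content at -0.47. The slope of each library's log2 values with GC content, per 10 percentage points, was -0.034, -0.015, 0.10 and 0.157 in DMSO 1 to 4 and -0.107, -0.037, -0.026 and -0.038 in Val-boroPro 1 to 4. The group means of 0.052 ± 0.092 and -0.052 ± 0.037 gave a two-sided exact permutation p of 0.057 (adjusted 0.095 over the 5 library measures). The number of genes with a read was 23835.5 ± 144 in DMSO and 23585 ± 89.8 in Val-boroPro (exact permutation p = 0.029, the smallest possible, adjusted 0.095). Exact permutation p-values were 0.43 for total reads and 0.14 for the share of the 10 most abundant genes (3.84% ± 0.26 and 3.59% ± 0.03).

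**Figure D3:**
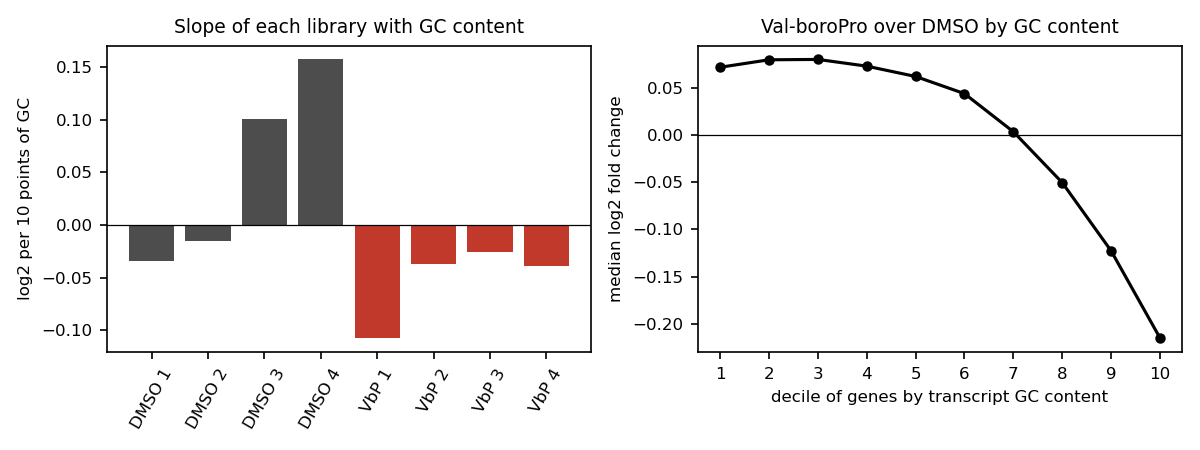
Left, slope of each library's log2 values with transcript GC content (log2 per 10 percentage points), DMSO in grey and Val-boroPro (VbP) in red. Right, median log2 fold change of genes in each decile by GC content, from 0.07 in the lowest to -0.22 in the highest.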

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

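Leaving out each library in turn was set beforehand, while the tests of GC slopes, length, trend removal, summed genes, list medians, crowding and other splits were chosen after the results they examine had been seen. Each library measure and each named gene was examined within DMSO and within Val-boroPro, which gave 204 sets of 4 values. Of these sets, 15 held a library far from the other 3, where chance gives about 5%. The sets share the same 8 libraries and many genes were picked by their values, so this share is no test. Of the 15, 9 were in DMSO and 6 in Val-boroPro, and DMSO 4 was the far library in 6. The value given for each is the gap to the nearest library over the whole range.

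Among library measures, DMSO 1 stood apart in total reads (40428711 against 34192806 to 35053304, 0.862), in genes with a read (24048 against 23730 to 23784, 0.8302) and in the size factor (1.34 against 1.15 to 1.17, 0.923). Val-boroPro 1 stood apart in the slope with GC content (-0.107 against -0.038 to -0.026, 0.844). Val-boroPro 1 was the far library for ASXL3 (0.857), PNPLA7 (0.864), MTHFD2 (0.851), MCL1 (0.9233) and FASN (0.879). DMSO 4 was the far library for ICAM5 (0.896), RPS6 (0.836), PSMD11 (0.8514), ATF3 (0.8292), NPEPL1 (0.847) and RP11-30L15.4 (0.902).

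GC-rich genes were lower in Val-boroPro, with a median log2 fold change of -0.22 in the most GC-rich decile. Transcript length in place of GC content is argued against, since with the length trend alone removed that median was -0.197 while that of all genes was 0.035. A GC bias of the libraries, whatever their group, may account for the pattern: slopes within DMSO spanned 0.191, more than the difference of -0.104 between the group means. An effect of the treatment on GC-rich transcripts cannot be told apart from it, since the mean slopes of 0.052 in DMSO and -0.052 in Val-boroPro gave a two-sided exact permutation p of 0.057, with DMSO 1 (-0.034) among the Val-boroPro slopes.

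Heat shock genes were higher in Val-boroPro. GC content and length as the whole cause are argued against, since the 14 called members stayed higher past the threshold once those trends were removed, among 15 called then. HSPA1A and HSPA1B summed had a log2 fold change of 0.50 (SE 0.040, adjusted p = 4.0e-06). HSPA1A had means of only 6.40 in DMSO and 14.6 in Val-boroPro, against 7978 and 11294 for HSPA1B. A shift of counted reads out of HSPA1A is thus argued against. The sum was bound to follow HSPA1B, so it cannot tell how reads matching both genes were assigned or dropped, which stays open. A single library is argued against as the whole cause, since the median log2 fold change of the list, 0.178, was still 0.163 without Val-boroPro 1, the lowest with 1 library left out, although the called members fell from 14 to 2 without Val-boroPro 1, Val-boroPro 2 or Val-boroPro 4 and to 3 without DMSO 3. Chance cannot be excluded for the median of 0.178, since the list was picked as the highest of 28, 2 of the 35 splits of the libraries, the real one among them, gave some list an absolute median as large (highest other 0.187), and camera passed for the heat shock list in 18 of the 34 other splits, although its own median was the largest in the real split (highest other 0.161). Whether the treatment acts on these genes remains a hypothesis, open beside differences between cultures, which were not tested.

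The count of called genes swung when 1 library was left out, to 3106, 81 and 523 without DMSO 1, 3 and 4 and to 6, 112, 2371 and 29 without Val-boroPro 1, 2, 3 and 4. Fewer libraries alone are argued against as the whole cause, since the highest of these counts, 3106, is above the count of 1533 with all 8. A GC bias of the libraries may account for part of it, since with GC and length trends removed the lowest count, without Val-boroPro 4, was 962, or 44.2% of 2177, in place of 0.39% of 1533. Adjusted p-values crowded at the threshold stay open: 1106 of the 1533 called genes had an adjusted p of at least 0.03, and the 1527 genes that lost the call without Val-boroPro 1 all kept their sign, with a median absolute log2 fold change of 0.18 in place of 0.21 and a median adjusted p of 0.126. The kept sign was largely given in advance, since the remaining libraries had helped to call these genes. No biological explanation was tested for this pattern.

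Chance is argued against, but not excluded, for the count of 1533 genes called by limma and for the 2177 called with GC and length trends removed. For each, 1 of the 35 splits, the real one, gave as many, which is the smallest share the splits can give. The highest of the other splits were 0 and 5. The gap was smaller at an unadjusted p below 0.05, with 5164 genes in the real split and 4299 in the highest other, DMSO 1 with Val-boroPro 1, 2 and 4 against the rest. The splits cannot tell the treatment from another difference between the groups of libraries. For the 4 genes with a large change the splits say nothing, since the other splits called no gene and their count of 0 was fixed by that. Chance cannot be excluded for the number of lists past the threshold, since 10 of the 35 splits gave at least 8 lists and the highest other gave 15.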

How the results depend on the processing

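The fits with GC and length trends removed and those without a pair of libraries were chosen after seeing the data. Under every alternative set beforehand and both fits without a pair of libraries the 1533 calls kept their sign where tested, and 1512 of 1521 did with GC and length trends removed. These fits reuse the libraries in which the genes were called, so the kept signs were largely given in advance. In total, higher, lower and at a large change, the calls were 1533, 816, 717 and 4. They were 803, 357, 446 and 16 with no filter (more tests), 310, 112, 198 and 0 after quantile normalization, 5, 1, 4 and 0 without trend, 3211, 1734, 1477 and 5 with the replicate number as a block, 7, 6, 1 and 0 at an adjusted p below 0.01, 62, 29, 33 and 0 without DMSO 4 and Val-boroPro 1, and 336, 160, 176 and 2 without DMSO 3 and DMSO 4. TMM factors gave 878 (308 higher, 570 lower), edgeR 796 (273 higher, 523 lower), DESeq2 1562 (695 higher, 867 lower) and GC removal 2177 (1603 higher, 574 lower), sharing 835, 771, 1272 and 988 genes with the 1533. Large changes numbered 0 with a pseudocount of 8, a mean of at least 50 or DESeq2. With 1 library left out the ranges were 6 to 3106, 5 to 1633, 1 to 1473 and 0 to 5, and 962 to 3837 with GC and length trends removed (1219 without DMSO 2, 1319 without DMSO 4, 1064 without Val-boroPro 1, 1228 without Val-boroPro 2, 3837 without Val-boroPro 3 and 962 without Val-boroPro 4). Beyond fewer samples, more tests, a stricter threshold and, for the fits with 1 library left out, the GC bias weighed above, the cause was not tested. Whether the replicate numbers pair the samples is not settled. Same-numbered libraries deviated together with correlations of 0.13, -0.03, -0.03 and 0.07 across genes, and other pairs with -0.20 to 0.10. The block on the replicate number nevertheless raised the calls from 1533 to 3211.

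Of the 24 genes that the rule named for the largest changes, 1 passed without trend, 2 to 23 with 1 library left out, 7 without DMSO 4 and Val-boroPro 1, and 12 without DMSO 3 and DMSO 4. Of the 85 called genes named in the text, 6 kept the call with each library left out, 60 with TMM factors, 58 with edgeR, 71 with DESeq2 and 72 of 83 with GC and length trends removed, none with another sign. Of these 72, 15 had a change smaller by over 1.5 times in that fit and 0 a larger one by that factor. The log2 fold change of DPP8 became 0.011 with median centring and -0.077 (SE 0.031, adjusted p = 0.092) with the trends removed. It ran from -0.030 to 0.020 with 1 library left out. DPP9 became 0.024 with the trends removed and 0.0028 without DMSO 3 and DMSO 4. CARD8 became -0.00034 without DMSO 3 and DMSO 4. None of these genes was past the threshold in these fits.

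The 8 lists past the threshold became 0 with an estimated correlation, 1 with fry, 13 with the trends removed, 14 without DMSO 3 and DMSO 4 and 8 to 13 with 1 library left out, where all 8 stayed past it each time. The other direction, with no call, was given (adjusted p) for inflammasome genes without DMSO 3 and DMSO 4 (0.995), endoplasmic reticulum genes by fry (0.946), cholesterol genes with TMM factors (0.953) and a mean of at least 50 (0.919), fatty acid genes with the block (0.858), TMM factors (0.906), a mean of at least 50 (0.894), the trends removed (0.618), without DMSO 4 and Val-boroPro 1 (0.750) and without DMSO 3 and DMSO 4 (0.405), p53 targets with the block (0.955), TMM factors (0.906) and a mean of at least 50 (0.894), NF-kB targets by fry (0.899), the trends removed (0.729), without DMSO 4 and Val-boroPro 1 (0.751) and without DMSO 3 and DMSO 4 (0.631), and immediate early genes with the trends removed (0.174), without DMSO 4 and Val-boroPro 1 (0.761) and without DMSO 3 and DMSO 4 (0.305). With 1 library left out these adjusted p-values ran from 0.396 to 0.993 for the integrated stress response, 0.761 to 0.993 for cholesterol, 0.699 to 0.993 for fatty acid genes, 0.761 to 0.993 for p53, 0.778 to 0.929 for NF-kB, 0.425 to 0.941 for immediate early genes and 0.669 to 0.993 for histones. The lowest correlation between libraries was 0.992 by Pearson and 0.993 by Spearman. The libraries did not group by treatment alone. DMSO 1 had a Pearson correlation of 0.9971 with DMSO 2 and 0.9968 with Val-boroPro 3, against 0.9959 and 0.9948 with DMSO 3 and DMSO 4. DMSO 2 had 0.9965 with Val-boroPro 3, against 0.9960 and 0.9951. On the first principal component, with 34.9% of the variance, DMSO ran from -24.3 to -0.48 and Val-boroPro from 3.33 to 22.1. At this depth a gene at the minimum mean of 10 rests on few reads, which limits what small changes can be seen there.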

Other observations

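The genes in this part were chosen after their values were seen and stand for no tested theme. The genes that kept the call with each library left out were HSPA1B, DNAJB1 and DUSP16, described above, VIM, the intermediate filament vimentin, from 8718 ± 262 to 10509 ± 263 (SD, n = 4; limma adjusted p = 0.0046), DTNA, dystrobrevin alpha, from 2112 ± 69.4 to 2571 ± 54.4 (limma adjusted p = 0.0051), and NOL12, a nucleolar protein, which fell from 594 ± 60.5 to 421 ± 15.5 (limma adjusted p = 0.0046). Other genes with low p-values were TAGLN2 (1.18-fold), PDLIM1 (1.22-fold) and TES (1.21-fold), which rose with limma adjusted p-values of 0.011, 0.0084 and 0.011 and each lost the call in 1 of the 8 fits without a library (highest adjusted p 0.051, 0.051 and 0.052). Of the CLK kinases, which phosphorylate splicing factors, CLK1, CLK3 and CLK4 fell by 0.28, 0.25 and 0.20 on the log2 scale (limma adjusted p = 0.016, 0.018 and 0.041, with overlapping groups for CLK4), and CLK2 had 3919 ± 132 and 3747 ± 253 (adjusted p = 0.36). With GC and length trends removed the log2 fold changes of CLK1, CLK3 and CLK4 were -0.32, -0.20 and -0.23, all past the threshold, and with 1 library left out the highest adjusted p was 0.086, 0.092 and 0.15.

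In total 491 genes (268 higher, 223 lower) were past the threshold in limma, in limma with GC and length trends removed, in edgeR and in DESeq2. Long non-coding genes made up 9.77% of the tested genes, 0.98% of the 816 called higher and 6.97% of the 717 called lower. With GC and length trends removed these shares were 10.0%, 0.81% of 1603 and 12.02% of 574, so that among lower genes the share went from below that of the tested genes to above it. In that fit, at a mean of 10 to 50, their median log2 fold change was -0.086 against -0.083 for protein-coding genes. With those trends removed the median log2 fold change was -0.053 for the 5390 genes with a mean under 200 and 0.036 for the 10690 others, a difference of 0.089 that was the largest of the 35 splits (highest other 0.079). Medians of the 23 chromosomes ran from -0.00075 to 0.035 in the same fit.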
